A study of Oryza sativa with 4 samples.

How the data were processed

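Total RNA of leaves from 2 WT and 2 OsBIERF3-OE samples was amplified to biotin-labelled cRNA and hybridized to 1 array each, per the labels' protocols, from 2 µg of RNA and plants grown at 28 °C for 14 h of light and 26 °C for 10 h of dark at 80 to 85% humidity. The labels call the replicates biological but do not say whether they came from separate plants or pools, so p-values measure only the spread between these samples. The deposited values are signal intensity per probe set on a linear scale, with 1 column per array. MAS5 is the only tool named, per the submitters' processing notes, with no version or role, and the normalization and the background correction are otherwise not given in the sources used here. On the log2 scale, the sorted values of an array lay within 0.0803 of the mean of the 4 arrays at the same rank, so the arrays had been brought to nearly one distribution before deposit, which would hide a global shift in RNA per cell. No detection calls were used here.

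Groups and replicate numbers came from the sample titles. Values were used as deposited, with a lower limit of 1, and put on the log2 scale. The 123 Affymetrix control probe sets were left out, and the upper 60% of the others by mean log2 signal over all 4 arrays, 34355 probe sets, were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend=TRUE) and Benjamini-Hochberg adjustment at 0.05. The design was genotype alone, and log2 changes are OsBIERF3-OE minus WT. The fit had 2 residual and 5.28 total degrees of freedom, and the median standard error of a log2 change was 0.152. Adjusted p-values in the text are limma's for probe sets and genes, and camera's for lists unless fry is named.

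Probe sets were named through the platform table and updated by gene ID to the RefSeq gene table of assembly GCF_034140825.1, joined in Python 3.11.15 with pandas 2.3.3. Of the probe sets, 22436 had 1 gene, 95 had several and were not named, and 34727 others are unnamed here. All 17905 genes matched the RefSeq table, and 2447 had a name other than an accession or clone. Coordinates were not used here. For 21 of the 1000 genes with several probe sets and a call, probe sets were called in opposite directions. For 616 of the 1000, some probe sets were called and others were not.

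Gene lists were tested with camera (preset inter-gene correlation 0.01), with 1 probe set per gene, the brightest on average, for the 34 of 35 lists with at least 5 measured genes. Camera with an estimated correlation kept 0 of the 9 calls. That version estimates the correlation from 2 residual degrees of freedom and tests on them, so it had little power here. Its unadjusted p for the 9 lists ran from 0.0587 for cell division to 0.513 for cell wall. Its 0 calls therefore do not show that correlation between genes accounts for the shifts, nor that it does not. Fry, whose directional p asks whether a list's genes move on balance one way and does not compare them with other genes, passed 10 lists, 5 of them camera calls in the same direction. The other 5, all lower in OsBIERF3-OE, were senescence, seed storage, ethylene, heat shock and the list of abscisic acid, cold and dehydration. Its mixed p, which asks for change in either direction, was not used for calls. Of the 35 lists, 24 had been fixed before the data were examined as searches of gene descriptions; as the tables used here hold names only, these lists were searched by gene name instead, and a list of NBS-LRR genes was dropped. The other 11 (clock, phosphate, iron, auxin, cytokinin, endoplasmic reticulum folding, chlorophyll and carotenoids, starch and sucrose, actin and tubulin, type 2C phosphatases, calcium-dependent kinases) were added after the names, the control probe sets of each array, some example rows and the correlations between arrays had been seen, but before any gene other than those was compared. The list medians, means and tests differed in sign for starch and sucrose, receptor-like kinases, auxin response and AP2/ERF genes.

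Named genes followed a rule fixed at the same time as the 24 lists, except that its filter on gene descriptions was replaced by one on gene names. For the largest changes this left 2218 of the 15981 genes tested. The rule takes the 8 largest fitted rises and falls among genes with a name, past the adjusted p and with the groups apart, and for each list up to 3 members past the test with the largest change, or the 2 with the smallest p where none passed. Further list members are named as examples after their values were seen. As a background level, chosen after seeing the data, the brightest of 33 control probe sets with no target in rice was taken on each array, at 25.1 to 28.0. Where a group's arrays were not above it, the fold is given as "at least", the bright group's mean log2 signal against the dim group's mean of the higher of that level and its own signal. Of the tested probe sets, 6271 were not above it on any array, and 270 of these passed the test. With dim signals raised to this level, the medians of pathogenesis-related, AP2/ERF and seed storage genes changed sign.

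The fit and the list test were tested on simulated data with 200 of 34355 probe sets changed, in 10 draws for each of 2 noise models. The first model took observed SDs as the true ones, which spreads the variances more than they are. A median of 0% of 2-fold and 41% of 4-fold changes were recovered, the latter ranging from 0% to 49%, and 2.09% of all calls were unchanged probe sets. The second model, with variances drawn from limma's fitted prior, was added after the first gave low recovery, as were the repeated draws. Its medians were 14.5% and 89%, and 6.31% of calls were unchanged. Camera found a list of 14 genes shifted by 1 on the log2 scale in 10 of 10 draws under both models, and 0 of 340 unshifted list tests passed in each. The simulated genes were independent, so this says nothing on correlated genes. The simulated share of changed probe sets was far below the 24.2% called in these arrays. As the Benjamini-Hochberg cutoff depends on that share, the recovery given here does not carry over to them.

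Alternatives were other scalings, filters on dim probe sets, floors, a pseudocount of 16, variance models, thresholds, a replicate block and leaving out each array. Those chosen after seeing the data were scaling on 21 hybridization control probe sets, a crossed block, a filter at the background level and list medians with dim signals raised to it.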

Results

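Gene expression was measured in leaves of 3-week-old rice plants (Oryza sativa) with 1-colour Affymetrix rice arrays. Plants that overexpress OsBIERF3 (OsBIERF3-OE), a transcription factor of the ethylene-responsive factor type, were compared with wild type (WT), with 2 arrays per genotype and no stress treatment. The median signal was 19.7 and 20.1 on WT arrays 1 and 2 and 20 and 20.3 on OsBIERF3-OE arrays 1 and 2, and the summed signal lay between 16286703 and 16466346. With 2 arrays per genotype, the number of arrays limits the precision of every value. The level of OsBIERF3 itself was not analysed here, so the genotype labels were not checked against the overexpressed gene.

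The comparison asks which leaf transcripts differ in level when OsBIERF3 is overexpressed under normal growth. In OsBIERF3-OE leaves 61 of 95 genes of the cell division list rose and 4 fell, and 21 of 24 named cytosolic ribosomal protein genes rose (adjusted p = 0.592 with an estimated correlation for both lists, which passed with the preset one). The test with an estimated correlation rests on 2 residual degrees of freedom and had little power for any list. The ratio of 3′ to 5′ signal of the actin and GAPDH controls, a sign of RNA or cRNA integrity, also differed between the genotypes, by up to 0.85 on the log2 scale. The mitotic cyclin gene CYCB1-1 (LOC4327547) rose 26.1-fold, from a signal of 47.7 ± 8.8 in WT to 1235 ± 8.5 in OsBIERF3-OE (SD, n = 2 each; limma adjusted p = 0.000234). By camera with its preset correlation, the lists of nutrient transporter, circadian clock and WRKY genes were shifted downward (adjusted p = 0.592 with an estimated correlation for each), and with the arrays scaled on hybridization controls the transporter and clock medians were closer to 0, at -0.05 and -0.17. Of 34355 probe sets tested, 8331 passed limma's adjusted p of 0.05, 4273 higher and 4058 lower in OsBIERF3-OE, and 3261 of the calls were at least 2-fold. At the gene level, 5074 of 15981 genes passed, 2755 higher and 2319 lower.

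Of the 8 rises named for their fitted change, 5 were in cell division genes; 6 of the 8 start from WT signals not above background, so their order was not measured. The mitotic cyclin gene CYCB2-2 (LOC4342121) rose from a signal of 12.3 ± 3.16 in WT to 623 ± 1.95 in OsBIERF3-OE (SD, n = 2 each), with a limma adjusted p of 0.000262. Its WT signal was not above that of control probe sets with no target in rice on either array, so the rise was at least 24.4-fold. MCM3 (LOC4339099), a subunit of the replicative helicase, rose at least 20.9-fold, and the kinesin gene STD1 (LOC4331094) at least 13.9-fold. CYCB1-1 was above the controls on all arrays. The kinesin gene KIN12C (LOC4333349), above the controls on 1 of the 2 WT arrays, rose from 26.3 ± 2.34 to 670.1 ± 27 (adjusted p = 0.000159). The other rises named were in KSL7 (LOC4329724), a diterpene synthase gene of phytocassane synthesis, at least 18.6-fold, KCS20 (LOC4348632), of very-long-chain fatty acid synthesis, at least 11.6-fold, and OFP8 (LOC4324787), an ovate family gene, at least 6.27-fold.

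**Figure D1:**
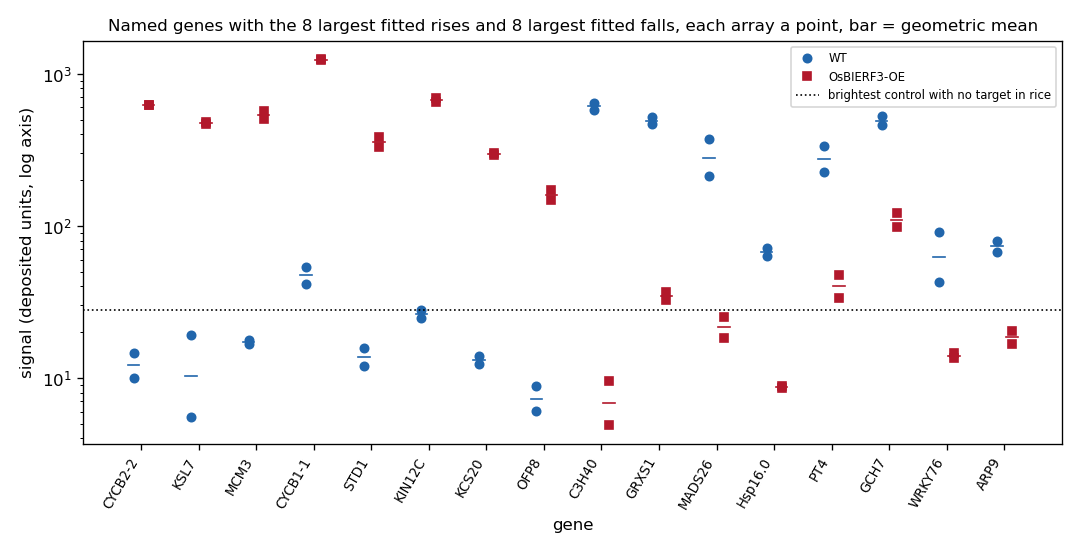
Signals of the 8 named genes with the largest fitted rise and the 8 with the largest fitted fall, in deposited units on a log axis, with WT arrays as circles, OsBIERF3-OE arrays as squares and short bars at the geometric mean of 2 arrays. The dotted line marks the brightest control probe set with no target in rice, at 28.0, and CYCB1-1 is the 1 rise of the 8 with both WT arrays above it.

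Of the 8 falls named for their fitted change, 5 end at signals not above background, so their order was not measured either. The zinc finger gene C3H40 (LOC4340263) fell from 612.3 ± 45.5 in WT to 7.23 ± 3.34 in OsBIERF3-OE (SD, n = 2 each), at least 22.4-fold, with a limma adjusted p of 0.000544. The glutaredoxin gene GRXS1 (LOC4327130) was 14.2-fold higher in WT, at 490.2 ± 37 against 34.5 ± 3.04. MADS26 (LOC4344493), a MADS-box transcription factor gene, was at least 10.3-fold lower and the small heat shock protein gene Hsp16.0 (LOC4340661) at least 2.46-fold lower in OsBIERF3-OE. The phosphate transporter gene PT4 (LOC4335115), read by a probe set possibly shared between genes, was 6.87-fold higher in WT, and the chitinase gene GCH7 (LOC4325148, also Cht10) 4.49-fold higher. WRKY76 (LOC4347069) and ARP9 (LOC4335089) were at least 2.28-fold and 2.68-fold lower in OsBIERF3-OE.

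Of 95 measured genes of the cell division list, 61 rose, 4 fell and 30 did not pass; adjusted over the list alone, 66 rose and 7 fell. The median log2 change was 1.25, and 1.005 with dim signals raised to the background controls (camera adjusted p = 4.29e-16 with the preset correlation, and adjusted p = 0.592 with an estimated correlation). The genes that rose include MCM2 to MCM7, PCNA, the origin recognition gene ORC1 and CDKB2-1, and among the kinesins KIN10C and KIN5C. Log2 changes were 3.42 for MCM2, 2.89 for PCNA and 3.39 for CDKB2-1. The list also holds growth-regulating factor genes, which encode transcription factors of leaf growth rather than parts of the cell cycle, and GRF10 rose at least 10.8-fold, GRF1 at least 8.67-fold and GRF7 at least 5.31-fold. The ratio of 3′ to 5′ signal of the actin and GAPDH control probe sets, a sign of RNA or cRNA integrity, also differed between the genotypes. It was lower on both OsBIERF3-OE arrays for 3 of 3 actin pairs, by 0.55 to 0.85 on the log2 scale, and for GAPDH it was 12.8 and 11.2 in WT against 7.37 and 7.25 in OsBIERF3-OE. The log2 ratio of ubiquitin differed by -0.27, and for cyclophilin, whose probe sets were higher in OsBIERF3-OE at both ends, the ratios of the genotypes overlapped.

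**Figure D2:**
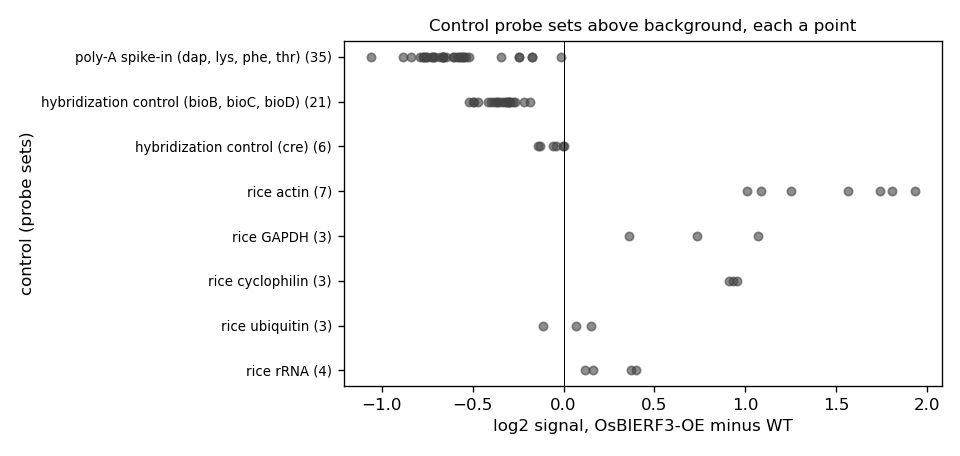
Log2 signal, OsBIERF3-OE minus WT, of the control probe sets above background, each a point, by kind of control. The 7 rice actin probe sets lie between 1.01 and 1.93, while the bioB, bioC and bioD hybridization controls have a median of -0.33.

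Of 24 measured cytosolic ribosomal protein genes, 21 rose, 0 fell and 3 did not pass (adjusted over the list alone, 21 rose and 1 fell). The median log2 change was 0.94 (camera adjusted p = 9.07e-09, and adjusted p = 0.592 with an estimated correlation). The widest gap between 5′ and 3′ changes of the rice control genes, 0.85 for actin, was close to this median. The acidic protein gene 60SP0 rose 2.76-fold, SS620 (also RPS4) 2.53-fold and RACK1A, a scaffold protein of the small subunit, 2.43-fold. In the list of protein folding in the endoplasmic reticulum, 8 of 22 genes rose, 1 fell and 13 did not pass (adjusted over the list alone, 9 and 1), with a camera adjusted p of 0.0249 and an adjusted p = 0.592 with an estimated correlation. Without WT replicate 2 the camera adjusted p was 0.0669. The disulfide isomerase-like genes PDIL2-1, PDIL4-1 and PDIL3-1 rose 2.25-fold, 1.97-fold and 1.84-fold. The list median of 0.21 was smaller than the 3′ to 5′ gap. Without WT replicate 2, PDIL4-1 (limma adjusted p = 0.0516) and PDIL3-1 (0.0798) did not pass, and without OsBIERF3-OE replicate 2 PDIL3-1 (0.069) did not.

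Among 82 genes of cell wall polysaccharide synthesis and loosening, 23 rose, 2 fell and 57 did not pass (adjusted over the list alone, 24 and 3). The median log2 change was 0.30 (camera adjusted p = 0.00471, and adjusted p = 0.65 with an estimated correlation). Without OsBIERF3-OE replicate 2 it was 0.14, with a camera adjusted p of 0.065, and with the arrays scaled on the hybridization controls 0.65. The median was smaller than the 3′ to 5′ gap of 0.85. The COBRA-like gene BC1L2 rose at least 5.68-fold, the endoglucanase genes GLU8 at least 3.12-fold and GLU13 8.23-fold, from 98.8 ± 67.3 to 721.3 ± 157 (SD, n = 2 each; limma adjusted p = 0.0151), and the expansin genes EXPB17 and EXPA6 had log2 changes of 3.03 and 2.22. The log2 change of GLU13 was 3.799 without WT replicate 1 and 2.28 without WT replicate 2. Of 35 actin and tubulin cytoskeleton genes, 14 rose, 3 fell and 18 did not pass (adjusted over the list alone, 16 and 4), with a camera adjusted p of 0.00624 and an adjusted p = 0.592 with an estimated correlation. That list was drawn up after the actin control probe sets had been seen to be higher in OsBIERF3-OE, so its direction is not independent evidence, and the 3′ to 5′ ratio of actin differed between the genotypes as given for the cell division genes. The beta-tubulin gene TUBB2 rose 7.39-fold, the formin gene FH2 at least 1.89-fold and the actin gene RAC3 2.49-fold.

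Of 81 aquaporin and nutrient transporter genes, 26 fell, 5 rose and 50 did not pass (adjusted over the list alone, 32 fell and 6 rose). The median log2 change was -0.40 (camera adjusted p = 0.00368, and adjusted p = 0.592 with an estimated correlation); with the arrays scaled on the hybridization controls it was -0.05, and with dim signals raised to the background controls -0.26. PT4 is named above, the potassium transporter gene HAK1, read by a probe set possibly shared between genes, was 3.53-fold higher in WT, and the ammonium transporter gene AMT1-1 had a log2 change of -1.71. The zinc transporter gene ZIP3 rose, from 20.5 ± 14.2 to 137.1 ± 79.4 (SD, n = 2 each; limma adjusted p = 0.0319), above the background controls on 1 of the 2 WT arrays, but did not pass without WT replicate 2 (0.0889) or OsBIERF3-OE replicate 2 (0.0913). In the iron list, which shares members with the transporters, 9 of 30 genes fell, 1 rose and 20 did not pass (adjusted over the list alone, 13 fell and 1 rose), with a camera adjusted p of 0.0155 and an adjusted p = 0.592 with an estimated correlation. Without OsBIERF3-OE replicate 2 the camera adjusted p was 0.065, and with no filter on dim probe sets 0.0881. The list median was -0.49, and -0.13 with the arrays scaled on the hybridization controls. The medians of the transporter and iron lists were both smaller in size than the 3′ to 5′ gap of 0.85. That gap was a larger rise of 5′ than of 3′ signals in OsBIERF3-OE, however, and whether it could lower a list was not tested. YSL13 and YSL16, of the yellow stripe-like metal chelate transporters, were 3.41-fold and 2.6-fold higher in WT, and the manganese transporter gene Nramp5 was the 1 gene that rose, 3.17-fold. Without WT replicate 2, YSL16 (limma adjusted p = 0.107) and Nramp5 (0.0637) did not pass, nor did YSL16 without WT replicate 1 (0.142). One of the 9 that fell, HSFA2D (log2 change -0.41), is a heat shock factor gene that the gene table also lists under a dioxygenase name of iron-deficiency responses.

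All 7 measured circadian clock genes had lower signals in OsBIERF3-OE; 5 fell and 2 did not pass (adjusted over the list alone, 6 fell). The median log2 change was -0.52 (camera adjusted p = 0.00953, and adjusted p = 0.592 with an estimated correlation), and -0.17 with the arrays scaled on the hybridization controls. In size this median was smaller than the 3′ to 5′ gap of 0.85, which was a larger rise of 5′ than of 3′ signals in OsBIERF3-OE. Whether that gap could lower the clock genes was not tested. The pseudo-response regulator genes PRR95 and PRR37 were 1.84-fold and 1.66-fold higher in WT and PCL1, an evening gene, 1.54-fold higher; without WT replicate 2 none of these 3 passed, with limma adjusted p of 0.0939, 0.0709 and 0.0595, and without OsBIERF3-OE replicate 2 PRR95 (0.067) and PRR37 (0.0557) did not. Of 6 WRKY genes, which encode transcription factors of defence and senescence, 4 fell and 2 did not pass (adjusted over the list alone, 5 fell). The median log2 change was -1.40, and -0.81 with dim signals raised to the background controls (camera adjusted p = 0.0249, and adjusted p = 0.592 with an estimated correlation). WRKY71 was 3.53-fold higher in WT and WRKY24 at least 2.08-fold, beside WRKY76.

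**Figure D3:**
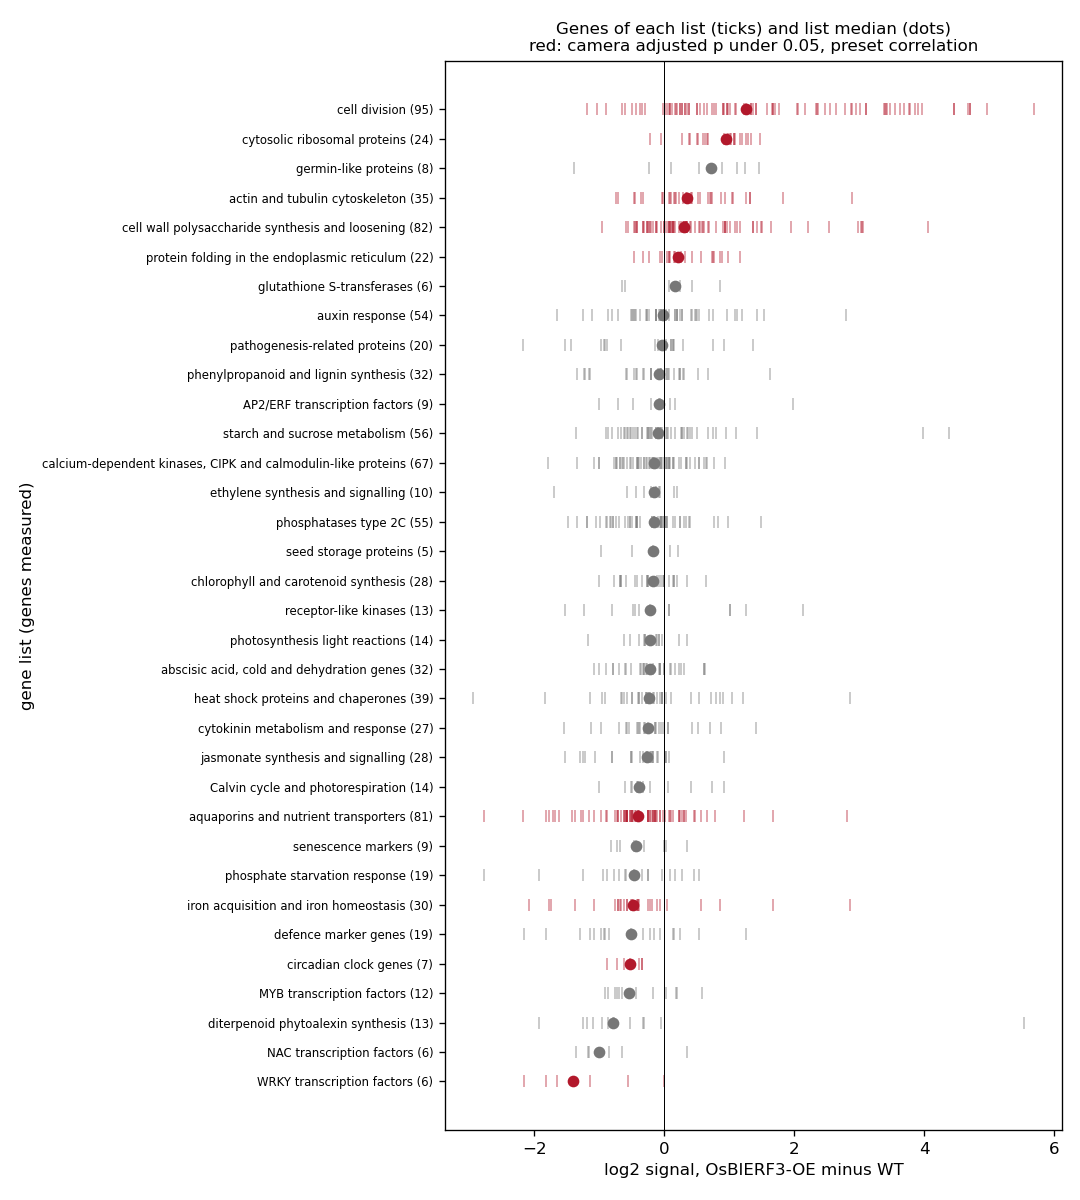
Log2 signal, OsBIERF3-OE minus WT, of each measured gene (ticks) of the 34 lists tested, with the list median as a dot and the number of genes measured in brackets. The 9 lists past the camera adjusted p of 0.05 with the preset correlation are red, from WRKY genes at a median of -1.40 to cell division genes at 1.25. With an estimated correlation, a test with little power at 2 residual degrees of freedom, 0 lists passed.

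No other defence gene list passed camera. Of 19 defence marker genes, WRKY71 and WRKY76 among them, 2 rose and 5 fell (camera adjusted p = 0.147; adjusted over the list alone, 2 and 5), and of 20 pathogenesis-related genes 2 rose and 1 fell (adjusted p = 0.711; alone, 2 and 1). CEBIP, a chitin receptor gene, rose 2.39-fold, and salT, a lectin gene of salt and drought responses, 2.58-fold. Of 13 genes of diterpenoid phytoalexin synthesis, 1 rose and 2 fell (adjusted p = 0.119; alone, 1 and 3); the rise was KSL7, while CYP71Z6 and KSL5 were 2.13-fold and 1.95-fold higher in WT. Phenylpropanoid and lignin synthesis had 1 rise and 5 falls among 32 genes (adjusted p = 0.268; alone, 1 and 5), with Os4CL2, a 4-coumarate ligase gene, 2.37-fold higher in WT. Germin-like genes had 4 rises among 8 (adjusted p = 0.119; alone, 4), led by GER1 at 2.73-fold. The receptor-like kinase list, which holds the receptor genes CEBIP and LYP4 and not kinases alone, had 4 rises and 3 falls among 13 (camera adjusted p = 0.881, alone 4 and 5). LYP4, a peptidoglycan and chitin binding protein gene, rose 4.39-fold. Glutathione S-transferases had 1 rise and 2 falls among 6 (camera adjusted p = 0.874, alone 1 and 2). Without WT replicate 2, CYP71Z6 (limma adjusted p = 0.0637) and KSL5 (0.107) did not pass, nor did KSL5 without OsBIERF3-OE replicate 1 (0.0764) or GER1 without OsBIERF3-OE replicate 2 (0.0615). Of the 2 class III peroxidase genes measured, too few for a list test, neither passed; PRX112 and PRX74 had log2 changes of 0.25 and 0.27.

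Hormone and stress lists did not pass camera either. By fry, the ethylene, heat shock and abscisic acid, cold and dehydration lists passed, lower in OsBIERF3-OE (fry adjusted p = 0.0375 for each). Jasmonate genes had 1 rise, LOX5 at 1.88-fold, among 28 (adjusted p = 0.116; alone, 0). Ethylene genes had 2 falls among 10 (adjusted p = 0.162; alone, 3), EIL1b and EIL1a, which encode EIN3-like transcription factors and were 3.26-fold and 1.36-fold higher in WT. The EIL1b signal was 1346 ± 245 in WT and 453.7 ± 277 in OsBIERF3-OE (SD, n = 2 each; limma adjusted p = 0.0451). Its log2 change of -1.71 was -2.37 without OsBIERF3-OE replicate 1 and -1.04 without OsBIERF3-OE replicate 2, and it did not pass without WT replicate 1 (limma adjusted p = 0.0969) or 2 (0.161). EIL1a did not pass whichever of the 4 arrays was left out, with limma adjusted p between 0.0701 and 0.144. Abscisic acid, cold and dehydration genes had 2 rises and 7 falls among 32 (adjusted p = 0.116; alone, 2 and 10), with the kinase gene SAPK1 2.12-fold higher in WT. Heat shock and chaperone genes had 6 rises and 8 falls among 39 (adjusted p = 0.162; alone, 6 and 8). AP2/ERF genes had 1 rise and 2 falls among 9 (adjusted p = 0.564; alone, 1 and 3), the rise being SMOS1, an organ size regulator, at 3.95-fold. NAC genes had 2 falls among 6 (adjusted p = 0.122; alone, 2), with NAC6 2.56-fold higher in WT, and MYB genes 1 rise and 4 falls among 12 (adjusted p = 0.129; alone, 1 and 4), with MYBS1 1.83-fold higher in WT. Without WT replicate 2, LOX5 (limma adjusted p = 0.0923), SAPK1 (0.0543), NAC6 (0.104) and MYBS1 (0.0507) did not pass, nor did NAC6 without WT replicate 1 (0.0924) or LOX5 without OsBIERF3-OE replicate 2 (0.0927).

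Photosynthesis, senescence and seed storage lists did not pass camera. By fry, the senescence and seed storage lists passed, lower in OsBIERF3-OE (fry adjusted p = 0.016 and 0.0193). Light reaction genes had 3 falls among 14 (adjusted p = 0.116; alone, 3), with the photosystem subunit gene PSAG 2.25-fold higher in WT. Calvin cycle and photorespiration genes had 2 rises and 6 falls among 14 (adjusted p = 0.122; alone, 3 and 9), and MOC2, a cytosolic fructose bisphosphatase gene of sucrose synthesis rather than of the Calvin cycle, was 2.01-fold higher in WT. Senescence markers had 2 falls among 9 (adjusted p = 0.144; alone, 2), RCCR1 and Lls1, of chlorophyll breakdown. Lls1 did not pass whichever of the 4 arrays was left out, with limma adjusted p between 0.0548 and 0.162. RCCR1 did not pass without WT replicate 1 (0.113), WT replicate 2 (0.0638) or OsBIERF3-OE replicate 2 (0.0973), nor MOC2 without WT replicate 2 (0.0509). Seed storage genes, markers of another tissue, had 2 falls among 5 (adjusted p = 0.28; alone, 2), with the glutelin gene Gt1 at 600.6 ± 3.27 in WT and 306.6 ± 16.7 in OsBIERF3-OE (SD, n = 2 each; limma adjusted p = 0.00645).

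The arrays of one genotype resembled each other more than those of the other genotype. Across the probe sets tested, which are not independent replicates, Pearson's r of the log2 signals was 0.9892 between the WT arrays and 0.9888 between the OsBIERF3-OE arrays, and between 0.9301 and 0.9479 across genotypes. Without any variance model, 2074 probe sets were at least 2-fold apart in every pair of a WT and an OsBIERF3-OE array, 1462 higher and 612 lower in OsBIERF3-OE. The other splits of the 4 arrays into 2 and 2 gave 3 and 17 such probe sets, but each puts 1 array of either genotype on both sides, so the genotype difference adds to its spread and the numbers do not measure chance. Controls that do not come from the leaves were also split by genotype. All 21 bioB, bioC and bioD probe sets and 35 of 36 poly-A spike-ins were lower on both OsBIERF3-OE arrays than on both WT arrays. These arrays cannot tell a genotype difference from a technical one aligned with it.

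The size of the count depended on how the variance was estimated and on single arrays. A test of each probe set on its own variance called 1 probe set after Benjamini-Hochberg adjustment and 8811 at an unadjusted p under 0.05, and limma called 4540 with a replicate block, 4337 without WT replicate 1, 3270 without WT replicate 2 and 3753 without OsBIERF3-OE replicate 2. Of the 101 probe sets named by rule, 99 passed with all arrays, 56 without WT replicate 2, 69 without WT replicate 1 and 67 without OsBIERF3-OE replicate 2. With the arrays scaled on the bioB, bioC and bioD hybridization controls, chosen after seeing the data, the median log2 change of all probe sets tested moved from -0.04 to 0.31 and the share of calls higher in OsBIERF3-OE from 51.3% to 86.9%, so the changes given here are relative to the deposited scaling. This scaling also moved the list medians of endoplasmic reticulum folding from 0.21 to 0.57 and of the cytoskeleton from 0.35 to 0.70.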

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

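The tests of array scaling, of the 3′ to 5′ difference and of the spike-in ratios were chosen after the results they bear on had been seen; the tests with marker and clock genes were set before, but the condition that a marker gene be above background was added after its value was seen.

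In control probe sets, which are outside the comparison of genes, those for actin, cyclophilin and GAPDH above background carried a signal that was higher on both OsBIERF3-OE arrays than on both WT arrays, 7 for actin and 1 for GAPDH by over 1 on the log2 scale. For actin the log2 changes were 1.01 and 1.25 for the 3′ probe sets of one design, 1.56 for its middle and 1.81 for its 5′ probe set, and 1.08, 1.74 and 1.93 for the 3′, middle and 5′ probe sets of the other. For GAPDH the 5′ probe set had a log2 change of 1.07, the middle 0.74 and the 3′ 0.36, and for cyclophilin the changes were 0.95, 0.94 and 0.91 from the 3′ to the 5′ end. The poly-A spike-ins, added to the RNA, had a lower mean log2 signal in OsBIERF3-OE for 36 of 36 probe sets, 35 of them lower on both arrays than on both WT arrays, with a median of -0.66, and the bioB, bioC and bioD hybridization controls were lower on both arrays for 21 of 21, with a median of -0.33, while cre had a median of -0.05.

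The rise of the cell division genes was kept under each scaling tried. Over the deposited, quantile, median-centred and hybridization-control scalings, the lowest list median was 1.23 on the log2 scale. This does not test scaling as its cause, since none of these could have removed a rise of that size. The deposited arrays already had nearly the same distribution, and the hybridization controls shifted the OsBIERF3-OE arrays up and the WT arrays down. At the deposited scaling the median log2 change of all probe sets tested was -0.04, so the rise was relative to other genes. The 3′ to 5′ difference remains open. The list median exceeded the widest gap between 5′ and 3′ changes of the rice control genes by 0.41, with a standard error of 0.21 that takes the genes as independent. This was too close to the margin set for excluding it, although 58 of 95 genes rose by more than that gap. With dim signals raised to background the list median was 1.005 against a gap of 0.85. Stem or shoot apex tissue in the OsBIERF3-OE samples remains open too, since the 5 knotted homeobox genes, all of them also in the cell division list, had a median change of 0.26, under the bound of 0.5 set for excluding it, but none was above background on any array, where a change cannot be read. A larger share of young leaf tissue is also open, with a median of 0.092 for 17 early chloroplast development genes. Its standard error, which takes the genes as independent, was 0.11, and the genes ranged from -0.714 to 0.674. An effect of genotype on cell division is a hypothesis that these arrays cannot separate from the part of the leaf sampled.

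For the lower 3′ to 5′ ratio of actin and GAPDH, shorter amplified cRNA in the WT labelling reactions would lower the ratio of the spike-ins in OsBIERF3-OE as well. Their mean log2 ratio differed by -0.10, with a standard error of 0.13 over the spike-in means, and phe was lower in 3 of 3 pairs while lys was higher in 2 of 3. The dimmest phe 5′ probe set read 29.5 and 33.4 in WT and 26.4 and 29.3 in OsBIERF3-OE, near the background controls. A fall at that end may not be readable there. The values decide neither for nor against it, and a difference in RNA integrity between the leaf samples was not tested.

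For the clock genes, a different time of day at harvest was set to predict opposite changes, over 0.5 each, of the morning gene LHY (listed as CCA1) and evening genes. LHY had a log2 change of -0.35, with a standard error of 0.22, and GI, PCL1 and PRR1 a median of -0.38. Both were lower, so the predicted opposite changes were not seen. This cannot exclude a different time of day, since the prediction need not hold at every hour and the sample details used here give no hour of harvest. LHY is also 1 gene and did not pass the test. With the arrays scaled on the hybridization controls the list median was -0.17, so how far the clock genes were lower depends on the scaling. An effect of genotype was not tested apart from this.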

How the results depend on the processing

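The scaling on hybridization controls, the crossed block and the filter at background level were chosen after seeing the data. The count of 8331 probe sets lay between 7504 and 8687 under quantile normalization, median centring, no filter or the upper 40%, the floor, the pseudocount and the other variance models, and at 8612 with the background filter and 10496 with the hybridization controls, where 9125 were higher and 1371 lower against 4273 and 4058. The filters changed the number tested, so the share called was less stable than the count. Calls were 7679 of 57258 with no filter, 7504 of 22903 in the upper 40% and 8612 of 26581 with the background filter, against 8331 of 34355. The count was 11873 at an adjusted p of 0.10, 3261 with a fold of at least 2 as well, and 1 with a plain two-sample t-test, which has no moderated variance. Leaving out 1 array, after which the lone array of a genotype is assumed to vary like the other group, gave 3270 to 6171. The 2-fold count of 2074 was 1513 to 2151 under the alternatives and 954 at 3-fold, the stricter fold.

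Replicate numbers were not taken as pairs: the labels name no shared batch, and the deviations of same-numbered arrays correlated at -0.249 across probe sets. A replicate block gave 4540 calls and the crossed replicate block 12339. With a negative correlation the same-number block leaves more residual variance and the crossed block less, so this order follows from it. The cause of the correlation was not tested.

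Of 34 lists, 9 passed, against 0 with an estimated correlation, 16 with hybridization-control scaling, and 9 to 14 without 1 array, the 14 without OsBIERF3-OE replicate 1; the cause was not tested. No list call turned direction under any alternative. Apart from the estimated correlation, the cell division, ribosomal, transporter and clock calls were kept under each alternative run; cell wall was lost without OsBIERF3-OE replicate 2 and by fry, iron without that array and with no filter, endoplasmic reticulum folding without WT replicate 2 and by fry, and WRKY and cytoskeleton by fry. WRKY had too few genes in the upper 40%. Of 101 probe sets named by the rule, 99 passed, 78 with the replicate block, 78 with hybridization-control scaling and 56 to 87 without 1 array, the 56 without WT replicate 2, and none turned direction. That none of these probe sets turned is no evidence of stability where an array was left out or a block was added. In each of the 99, both arrays of one genotype exceeded both of the other, so these alternatives could not turn the direction. The alternatives planned for the OsBIERF3 level gave no value. Signals near those of controls with no target limit folds of dim genes to bounds.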

Other observations

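Lists added after the gene names were seen hold further changes. Of 66 auxin response genes on the array, 54 were measured; 10 rose and 4 fell (camera adjusted p = 0.695; adjusted over the list alone, 10 and 4), with the Aux/IAA gene IAA14 at 32.1 ± 13.6 in WT and 214.8 ± 29.2 in OsBIERF3-OE (SD, n = 2 each; limma adjusted p = 0.00595) and the efflux carrier gene PIN3a, read by a probe set possibly shared between genes, at 2.89-fold, while SAUR39 was 3.15-fold higher in WT. Among 56 starch and sucrose genes, 6 rose and 7 fell (adjusted p = 0.564; alone, 10 and 9), and the rises were led by the cell wall invertase gene CIN2, at least 11-fold, and the sucrose transporter gene SWEET11, read by a probe set possibly shared between genes, at 15.8-fold, from 68.8 ± 60.5 to 863.4 ± 215 (SD, n = 2 each; limma adjusted p = 0.0164). The log2 change of SWEET11 was 5.03 without WT replicate 1 and 2.93 without WT replicate 2. Of 19 phosphate starvation genes, 1 rose and 4 fell (adjusted p = 0.122; alone, 1 and 5), among them the transporter genes PT4, PT8 and PT1, of which PT4 and PT8 are read by probe sets possibly shared between genes. Without 1 array, SAUR39 did not pass 3 times (limma adjusted p = 0.051 to 0.102; it passed without OsBIERF3-OE replicate 1), PT1 without WT replicate 1 (0.0513) or 2 (0.0694), and PIN3a without OsBIERF3-OE replicate 2 (0.0509).

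Type 2C phosphatases had 4 rises and 15 falls among 55 genes (camera adjusted p = 0.0514; adjusted over the list alone, 4 and 18), and calcium-dependent kinase, CIPK and calmodulin-like genes 7 and 16 among 67 (adjusted p = 0.147; alone, 8 and 18). Chlorophyll and carotenoid genes had 0 rises and 8 falls among 28 (adjusted p = 0.129; alone, 8), including the phytoene synthase genes PSY1 (read by a probe set possibly shared between genes), PSY2 and PSY3 and the zeaxanthin epoxidase gene ABA1. Without 1 array, ABA1 passed only without OsBIERF3-OE replicate 1 (limma adjusted p = 0.0826 to 0.176 for the others) and PSY3 only without WT replicate 2 (0.092 to 0.119 for the others). Cytokinin genes had 3 rises and 2 falls among 27 (adjusted p = 0.268; alone, 3 and 2); RR5 passed the test, but its signals were not above the background controls in either genotype.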
